A study of Rattus norvegicus with 9 samples.

How the data were processed

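The samples were peripheral blood mononuclear cells (PBMC, the lymphocytes, monocytes and other nucleated cells left after most red cells and granulocytes are removed) of wild-type Sprague-Dawley rats. The 9 libraries form 3 groups of 3: normoxia at day 0, and Sugen-hypoxia at day 28 and at day 56. Sugen-hypoxia is a rat model of pulmonary hypertension that combines an inhibitor of VEGF receptors with a period of low oxygen. Per the labels' protocols, RNA was taken up in Trizol, purified on PureLink columns with a DNase step, and made into Illumina libraries. The only controls are the day 0 rats, so day, age and treatment cannot be separated. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

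The authors deposited 1 table of gene expression for the whole series. Per the file headers, it gives for each Ensembl gene the exon reads, the uniquely mapped exon reads, the exon plus intron reads and the RPKM (exon reads scaled by exon length and mapped reads) of each library. Per the submitters' processing notes, the reads were mapped to rn6 and FastQC was used; the aligner and its settings are not given in the sources used here. The deposited exon reads are raw counts and include reads that map to several places. In the columns of replicate 1 of each group, the deposited values are also whole counts on every intact line, but a fraction from a broken line made them formally estimated counts; no rounding was needed. The RPKM values were computed by the authors and were used here only to recover the mapped reads behind them. Coordinates are those of the file on rn6. Of 22085 lines, 22077 held intact genes; the genes Bmp4, Ctnnb1, Shh and Wnt5a were broken over 8 lines and left out. In 25 lines the symbol had been turned into a date, and 262 symbols carried a suffix for another locus; genes were therefore handled by their Ensembl identifier. A RefSeq table of another assembly (GRCr8) was used only for names and held 16649 of the symbols. The table has 90 further columns of values per sample that were not used.

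Exon reads per library ranged from 22148400 to 39947430. A count of 3 reads corresponded to between 0.0751 and 0.135 CPM (counts scaled to a common total of exon reads). This range is without the TMM factors that the CPM values and group floors below use, so it does not apply to them directly. Floors and counts cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise, so each counted as 1 sample.

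Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust glmQLFit and glmQLFTest, TMM factors, the default filterByExpr filter) in R 4.3.3, with 1 mean per group over all 9 libraries. P-values were adjusted by the Benjamini-Hochberg method at 0.05 over the 12447 genes that passed the filter. The common biological coefficient of variation was 0.280. CPM values use the TMM-scaled library sizes, and standard errors (SE) of log2 fold changes were derived from the F statistic. Against a group with 0 reads in all libraries, a fold is the mean CPM of the other group over a limit of 3 counts in the whole group at 0. It is a lower bound only for that mean and does not cover the spread of its libraries. Each of 31 gene lists was tested in each of 3 comparisons with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the 93 tests; camera with an estimated correlation and fry were run beside it. The calls of no list held with an estimated correlation. Fry made 7 calls, 3 at day 28 and 4 at day 56, all up. They were AHR targets, immediate-early and glucocorticoid response genes at both days, and circadian clock genes at day 56. Fry asks only whether a list moves on balance in 1 direction. In 100 splits of the 9 libraries into 3 groups of 3 (closing section), the median split gave 31 list calls at the preset correlation, against the real 38.

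The lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists were AHR pathway components, AHR target genes, BMP and TGF-beta response, NF-kB inflammatory genes, glucocorticoid response, hypoxia (HIF) targets, heat shock, immediate-early genes, interferon-stimulated genes, circadian clock, cell cycle, chemokine receptors, genes of inherited pulmonary hypertension, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, MHC class II, and markers of B cells, T cells, T helper 17 cells, regulatory T cells, NK and cytotoxic cells, plasma cells, monocytes, dendritic cells, neutrophils, myeloid suppressor cells, basophils with eosinophils and mast cells, erythroid cells, platelets, and endothelial or stromal cells. The named genes were Ahr, Arnt, Ahrr, Cyp1a1, Cyp1b1, Tiparp and Nqo1 whatever their result; per comparison, the 8 largest rises and the 8 largest falls among called genes with a proper symbol, a mean log2 CPM above 1 and groups that did not overlap; and the 2 members with the smallest p of each list in which at least 2 passed.

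On simulated counts with 200 changed genes, the day 28 test recovered 26% of 2-fold and 92% of 4-fold changes among 12368 genes tested, and called 7 unchanged genes. The day 56 test recovered 30% and 85% among 12319 genes with 4 unchanged genes called, and the comparison of both days 27% and 89% among 12258 genes with 5. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (1 CPM in all libraries of a group and a mean of 5 CPM), globin and mitochondrial genes out of the library sizes, the replicate number as a block, only the groups compared, an adjusted p of 0.01, a 2-fold minimum, and each library left out in turn. Others were added after seeing the data and are named as such in the closing section. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.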

Results

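RNA sequencing profiled peripheral blood mononuclear cells of Sprague-Dawley rats kept in normoxia (day 0) and of rats in the Sugen-hypoxia model of pulmonary hypertension at day 28 and day 56. Each group had 3 libraries, with 22148400 to 39947430 exon reads each. The title of the series is about the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, in pulmonary arterial hypertension. The comparisons ask which transcripts of circulating mononuclear cells differed from normoxia at each day, and which differed between the days.

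The libraries held different amounts of red cell RNA. The 5 genes with the most reads, all in the globin loci, took 49.5% ± 6.65 (SD, n = 3) of exon reads in normoxia, 11.7% ± 15.01 (SD, n = 3) at day 28 and 42.7% ± 2.01 (SD, n = 3) at day 56. At day 28 the share was 1.42% in replicate 1, 4.83% in replicate 2 and 29.0% in replicate 3. Intron reads made up 8.86% ± 5.02 (SD, n = 3) of the reads in genes in normoxia, 20.2% ± 5.45 (SD, n = 3) at day 28 and 14.3% ± 2.48 (SD, n = 3) at day 56. Normoxia replicate 1 had 14.6% intron reads, against 6.60% and 5.37% in the other normoxia libraries. The first principal component (40.6% of variance) separated normoxia replicates 2 and 3 from all other libraries, normoxia replicate 1 included, and the second (22.7%) separated day 56 from the rest.

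**Figure D1:**
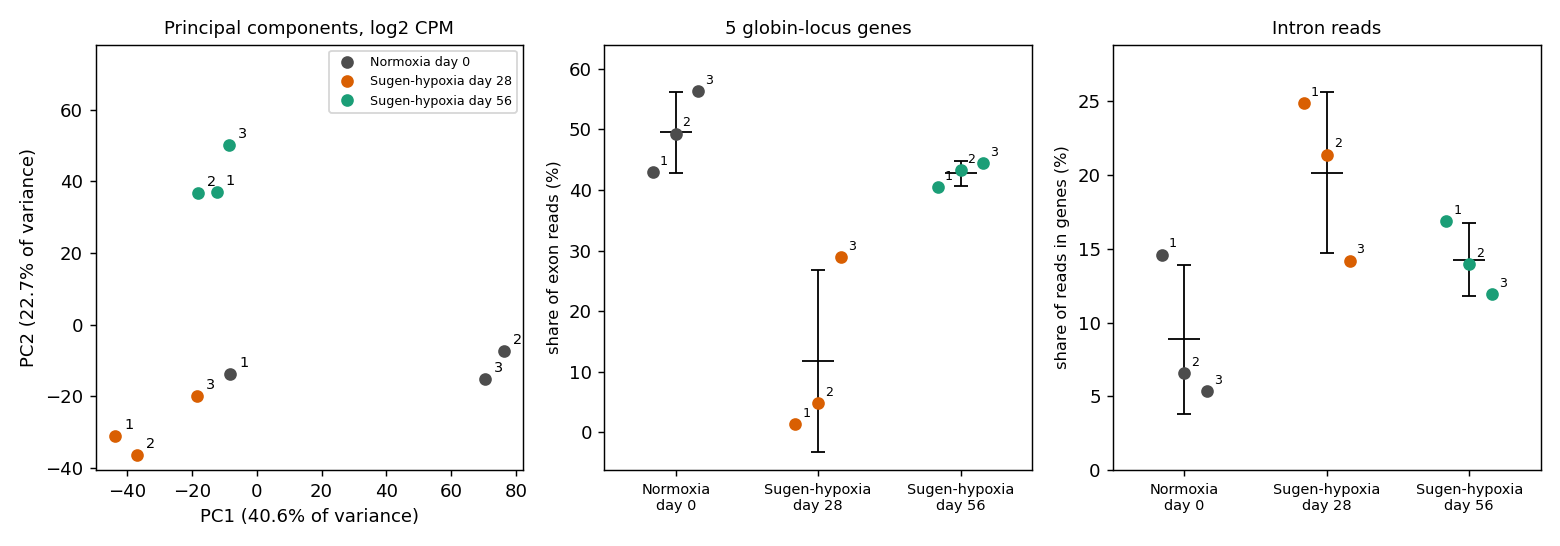
Left, the 9 libraries on the first 2 principal components of log2 CPM; middle, the share (%) of exon reads in the 5 globin-locus genes; right, the share (%) of reads in genes that lie in introns. Points are libraries with their replicate numbers, and bars are mean ± SD of 3 libraries. Normoxia replicates 2 and 3 lie apart on the first component, and day 28 replicates 1 and 2 hold the lowest globin shares (1.42% and 4.83%).

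Ahrr, the repressor that AHR itself induces, was not detected in normoxia and was present in all 6 Sugen-hypoxia libraries. Ahrr (ENSRNOG00000014721, chromosome 1, 31603296 to 31698329, rn6) had 0 exon reads in all 3 normoxia libraries, which allows up to 0.0450 CPM (3 counts over the group). It had 246, 179 and 110 reads at day 28 and 86, 133 and 118 at day 56, which is 4.87 ± 1.54 and 4.25 ± 1.22 CPM (SD, n = 3). The mean of Ahrr was at least 108-fold higher at day 28 (adjusted p = 0.00609) and at least 94.4-fold higher at day 56 (adjusted p = 0.00161). Between the days the log2 fold change of Ahrr was -0.20 (SE 0.34, adjusted p = 0.819). Without any 1 library the call of Ahrr held at both days. It was lost at day 28 in 4 of 22 alternatives. The adjusted p at day 28 ran from 1.84e-10 to 0.103, the latter with the intron share as a covariate, a choice made after seeing the data. The fitted log2 fold change of Ahrr, which depends on the prior count and is no bound, was 10.11 without that covariate and 9.48 with it.

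Nqo1, an AHR and oxidative stress target, went from 4.38 ± 1.51 CPM to 13.6 ± 2.82 CPM (SD, n = 3) at day 56, a log2 fold change of 1.64 (SE 0.35, adjusted p = 0.0289). That call was lost without normoxia replicate 2 (adjusted p = 0.109) or 3 (0.0521) without day 56 replicate 1 (0.0629), 2 (0.113) or 3 (0.0924), and with the intron share as a covariate (0.132; log2 fold change 1.58, SE 0.45). At day 28 Nqo1 stood at 20.3 ± 8.25 CPM (SD, n = 3) and did not pass (log2 fold change 2.23, SE 0.35, adjusted p = 0.0534), although its 3 values lay above all 3 of normoxia. It passed in 7 of 23 alternatives: with upper-quartile factors (0.0473), DESeq2 (5.84e-07), no filter (0.0223), the replicate block (0.0309) and uniquely mapped reads (0.0480), and without normoxia replicate 1 (0.00392) or day 28 replicate 3 (0.00635). The adjusted p reached 1 with the intron share as a covariate. Ahr itself was at 10.4 ± 0.600, 14.9 ± 1.13 and 14.96 ± 2.60 CPM (SD, n = 3) in normoxia, at day 28 and at day 56. Its log2 fold change was 0.53 at both days and did not pass (adjusted p = 0.111 and 0.0840), although its 3 values at each day lay above all 3 of normoxia. The lowest adjusted p of Ahr over the alternatives was 0.0376 at day 28 and 0.0333 at day 56, so the miss depends on the setting. Arnt, the partner of AHR, had log2 fold changes of 0.38 (adjusted p = 0.188) and 0.20 (adjusted p = 0.477), and Tiparp 0.80 (adjusted p = 0.104) and 0.37 (adjusted p = 0.327). Over the alternatives the lowest adjusted p of Arnt was 0.00313 at day 28 and 0.0164 at day 56. For Tiparp it was 0.0327 at day 28 and 0.251 at day 56. The AHR targets Cyp1a1 and Cyp1b1 had too few reads to be tested: Cyp1a1 had 2, 20 and 10 reads over the 3 libraries of normoxia, day 28 and day 56, and Cyp1b1 had 1, 8 and 9.

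The AHR target list rose at day 56 (camera adjusted p = 0.00118, or 0.306 with an estimated correlation, and 0.000581 with fry). Of its 7 tested members 5 rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell. Ahrr and Nqo1 are given above. The others that rose, outside the naming rule and named after their values were seen, were Scin (1.60, SE 0.37, adjusted p = 0.0362), Cyp2s1 (1.12, SE 0.27, adjusted p = 0.0407) and the amino acid transporter Slc7a5 (1.00, SE 0.24, adjusted p = 0.0407). At day 28 the list rose (camera adjusted p = 0.0408, or 0.567 with an estimated correlation, and 0.00141 with fry). Ahrr was the 1 member past the threshold, and 3 were higher and 1 lower adjusted over the list alone. The median log2 fold change was 0.45. The mean of 1.65 includes the fitted 10.11 of Ahrr. Without normoxia replicate 1 the list was not called at day 28 (adjusted p = 0.318) or at day 56 (adjusted p = 0.0834), and without day 28 replicate 2 not at day 28 (adjusted p = 0.0602). With the replicate number as a block its day 28 call was also lost (adjusted p = 0.0719).

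**Figure D2:**
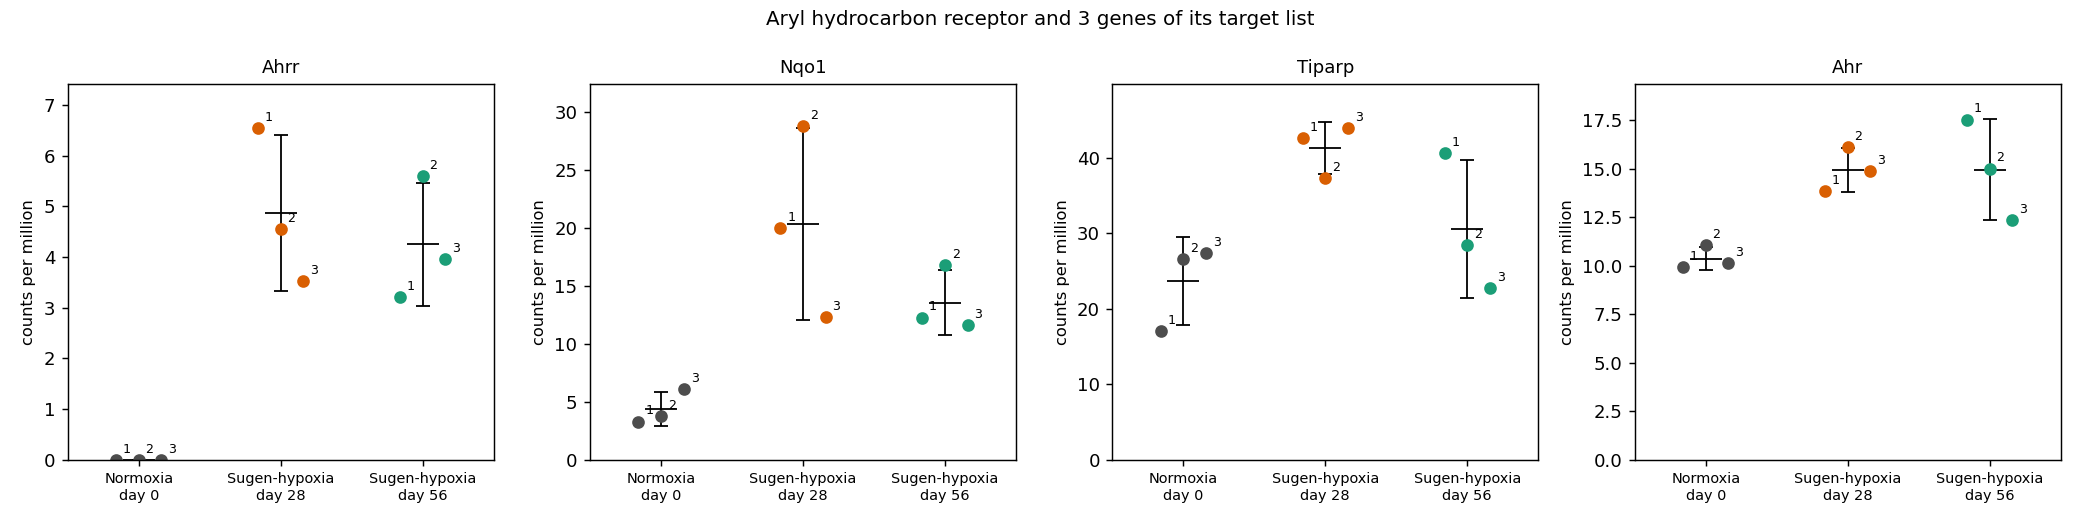
CPM of Ahrr, Nqo1, Tiparp and Ahr in each library, by group. Points are libraries with their replicate numbers, and bars are mean ± SD of 3 libraries. Ahrr is at 0 in the 3 normoxia libraries and between 3.21 and 6.54 CPM in the 6 Sugen-hypoxia libraries.

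At day 28, 11 genes rose and 5 fell against normoxia. Fam111a, a protease gene linked to antiviral defence, rose from 3.07 ± 1.55 to 176 ± 62.4 CPM (SD, n = 3), a log2 fold change of 5.86 (SE 0.53, adjusted p = 0.00609). Erp27, an endoplasmic reticulum protein, rose by 3.67 (SE 0.35, adjusted p = 0.00609). Tnfaip3, the feedback inhibitor of NF-kB, rose by 2.77 (SE 0.36, adjusted p = 0.0450), the AP-1 component Jun by 2.59 (SE 0.35, adjusted p = 0.0450), the homing receptor Gpr15 by 2.04 (SE 0.28, adjusted p = 0.0450), Rhob by 1.73 (SE 0.18, adjusted p = 0.00808) and the transcription factor Klf6 by 1.37 (SE 0.14, adjusted p = 0.00609). Dpysl5 rose by 2.13 (SE 0.32, adjusted p = 0.0464), but only 11.7% of its exon reads were uniquely mapped, so its value is uncertain. The named genes that fell were the centromere gene Cenpw (-3.03, SE 0.45, adjusted p = 0.0464), Phf7 (-1.81, SE 0.27, adjusted p = 0.0464) and the mitochondrial iron carrier Slc25a37 (-1.55, SE 0.21, adjusted p = 0.0459), which is on the erythroid list.

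The list calls here and below do not set these groups apart from a random grouping: 17 of 100 splits gave at least the real 38 calls. Immediate-early genes, the transcription factors and regulators switched on within minutes of a stimulus, rose together at day 28 (camera adjusted p = 1.70e-12, or 0.462 with an estimated correlation, and 0.0128 with fry). Their median log2 fold change was 1.18, 29 of 30 were higher, 3 passed over all genes and 23 adjusted over the list alone. NF-kB inflammatory genes rose (adjusted p = 8.82e-06; adjusted p = 0.625 with an estimated correlation), with 1 of 28 members past the threshold and 14 higher and 1 lower adjusted over the list alone. Monocyte markers rose (camera adjusted p = 6.68e-06, or 0.675 with an estimated correlation), with 0 of 36 past the threshold over all genes and 13 higher and 1 lower adjusted over the list alone. Their mean log2 CPM was 5.93, 6.75 and 5.51 at day 28, against 5.32, 4.80 and 5.55 in normoxia. Day 28 replicate 3 thus lay within the normoxia range. Myeloid suppressor genes (adjusted p = 0.00106; 0.625 with an estimated correlation; 6 of 11 higher adjusted over the list alone) and BMP and TGF-beta response genes (adjusted p = 0.00186; 0.625 with an estimated correlation; 6 higher and 1 lower of 15) rose as lists with 0 members past the threshold over all genes. So did glucocorticoid response genes (camera adjusted p = 0.00526, or 0.426 with an estimated correlation, and 0.0232 with fry), with 3 of 12 higher adjusted over the list alone. Camera did not call them without normoxia replicate 1 (adjusted p = 0.118). Neutrophil markers rose (adjusted p = 0.0340; 0.740 with an estimated correlation) with 0 of 22 members past either threshold, and not without normoxia replicate 1 (0.340), normoxia replicate 2 (0.106) or day 28 replicate 2 (0.314). With day 28 replicates 1 and 2 left out together, a choice made after seeing the data, monocyte (adjusted p = 0.0597) and neutrophil markers (0.0977) were not called.

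Erythroid markers fell at day 28 (camera adjusted p = 1.90e-17; adjusted p = 0.625 with an estimated correlation), alongside the globin share given above. Their median log2 fold change was -2.67, 39 of 40 were lower, 1 passed over all genes and 33 adjusted over the list alone. Their mean log2 CPM was 5.93, 7.06 and 7.35 in the normoxia libraries, 2.67, 3.71 and 5.38 at day 28 and 6.43 to 6.65 at day 56, so normoxia replicate 1 lay below the day 56 libraries and day 28 replicate 3 above the other day 28 libraries. Platelet markers fell (adjusted p = 1.20e-06; 0.713 with an estimated correlation; median -1.43), with 0 of 38 past the threshold over all genes and 28 lower and 1 higher adjusted over the list alone. Ribosomal protein genes (adjusted p = 9.91e-07; 0.740 with an estimated correlation; median -0.80) and nuclear oxidative phosphorylation genes (adjusted p = 4.34e-05; 0.740 with an estimated correlation; median -0.58) fell as lists with 0 members past either threshold. Normoxia replicate 1 also lay apart from the other normoxia libraries in the platelet, ribosomal and oxidative phosphorylation lists. The mean log2 CPM of ribosomal protein genes was 8.35 in normoxia replicate 1, 9.66 and 9.68 in normoxia replicates 2 and 3, and 8.65 to 8.95 in the 6 Sugen-hypoxia libraries. The oxidative phosphorylation mean was 5.11, 6.14 and 6.18 in the normoxia libraries and 5.14 to 5.43 in the Sugen-hypoxia libraries. The platelet mean was 4.45, 6.14 and 6.24 in the normoxia libraries and 4.15 to 4.89 at day 28. With the intron share as a covariate these 3 lists turned upwards at day 28 (adjusted p = 9.91e-05 for ribosomal, 0.0850 for platelet and 0.584 for oxidative phosphorylation genes). Cell cycle genes fell (adjusted p = 0.000428; 0.652 with an estimated correlation), with 0 of 42 past the threshold over all genes and 4 lower adjusted over the list alone. B cell markers fell (adjusted p = 0.00529; 0.740 with an estimated correlation), with 0 of 22 past the threshold over all genes and 1 adjusted over the list alone, and not without normoxia replicate 1 (0.0761) or day 28 replicate 3 (0.113). With the intron share as a covariate the day 28 calls of cell cycle genes (0.0575) and of BMP and TGF-beta response genes (0.374) were lost.

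In all, 16 of 12447 genes passed at day 28, 3582 had an unadjusted p under 0.05, and the groups did not overlap in 23.2% of genes, where chance gives 10% on average. Genes are not independent within libraries, so the share in 1 grouping can lie far from that average. Its spread was not computed in any comparison. The count of 16 was 5732 without normoxia replicate 1, 389 without day 28 replicate 3 and 2 to 6 without any 1 of the other libraries, and DESeq2 called 1762. With the intron share or the globin share as a covariate, both chosen after seeing the data, 1 gene passed, Fam111a, and 11 of the 12 named calls were lost. The globin share entered as its log2 value here and below. All 16 genes kept their sign, with a median of 0.768 and 0.870 times the log2 fold change and 1.45 and 1.38 times the SE. Upper-quartile factors gave 31 higher and 48 lower and RLE factors 8 higher and 0 lower. All day 28 libraries share 1 series of column codes, so that series and day 28 cannot be told apart. Of the 12 named genes called, only Ahrr and Fam111a passed without each library in turn. The calls lost numbered 8 and 10 without normoxia replicates 2 and 3, 9 and 7 without day 28 replicates 1 and 2, and 7 without any 1 of the day 56 libraries, with adjusted p up to 0.169.

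At day 56, 426 genes were higher and 460 lower than in normoxia. Immediate-early genes rose as a list (camera adjusted p = 3.89e-19, or 0.306 with an estimated correlation, and 0.00141 with fry). Of them 24 of 30 passed over all genes and 26 adjusted over the list alone, all higher, with a median log2 fold change of 1.87. Fosb, an AP-1 component, rose from 2.78 ± 1.34 to 86.8 ± 12.1 CPM (SD, n = 3), by 4.95 on the log2 scale (SE 0.58, adjusted p = 0.00404). Nr4a2 rose by 5.46 (SE 0.85, adjusted p = 0.0112), Rhob by 2.61 (SE 0.19, adjusted p = 0.000440) and Klf6 by 1.91 (SE 0.14, adjusted p = 0.000440). Of NF-kB inflammatory genes 9 of 28 rose and 1 fell (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.12e-05; adjusted p = 0.625 with an estimated correlation). Tnfaip3 rose from 45.3 ± 13.7 to 792 ± 87.6 CPM (SD, n = 3), by 4.13 (SE 0.39, adjusted p = 0.00134), and the NF-kB subunit Rel by 2.16 (SE 0.26, adjusted p = 0.00493). Ptgs2, the inducible prostaglandin synthase, rose by 4.16 (SE 0.91, adjusted p = 0.0307) and the chemokine Cxcl2 by 4.13 (SE 0.81, adjusted p = 0.0232), while the cytokine Il18 fell by 2.48 (SE 0.46, adjusted p = 0.0198).

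Glucocorticoid response genes rose at day 56 (camera adjusted p = 0.000158, or 0.306 with an estimated correlation, and 0.00278 with fry), with 3 of 12 past the threshold and 4 adjusted over the list alone. Per1, a clock gene that glucocorticoids induce, rose from 26.4 ± 9.62 to 344 ± 18.3 CPM (SD, n = 3), by 3.70 (SE 0.40, adjusted p = 0.00286), and Klf9 rose by 2.48 (SE 0.35, adjusted p = 0.00748). Circadian clock genes rose (camera adjusted p = 0.00245, or 0.510 with an estimated correlation, and 0.0193 with fry), with 4 of 14 past the threshold and 5 adjusted over the list alone. Among them were Nfil3 (2.07, SE 0.42, adjusted p = 0.0249) and Ciart (3.19, SE 0.65, adjusted p = 0.0257). No label gives the hour of sampling. Hypoxia targets rose as a list (adjusted p = 0.0282; 0.625 with an estimated correlation), with 5 of 28 higher and 1 lower (6 and 1 adjusted over the list alone). Vegfa, the endothelial growth factor, rose by 3.02 (SE 0.45, adjusted p = 0.00985) and Bhlhe40 by 2.15 (SE 0.36, adjusted p = 0.0147). The hypoxia list was not called without normoxia replicate 1 (0.301) or day 56 replicate 3 (0.0546), nor with the replicate number as a block (0.0554). Myeloid suppressor genes (adjusted p = 0.00345; 0.625 with an estimated correlation) rose with 4 of 11 past the threshold and 5 adjusted over the list alone, Vegfa and the checkpoint ligand Cd274 (1.45, SE 0.25, adjusted p = 0.0164) among them. BMP and TGF-beta response genes rose (adjusted p = 0.00572; 0.628 with an estimated correlation) with 2 of 15 higher and 1 lower (6 and 1 adjusted over the list alone): Tgif1 rose by 1.00 (SE 0.20, adjusted p = 0.0239) and Id3, a direct BMP target, fell by 1.54 (SE 0.25, adjusted p = 0.0132). With the intron share as a covariate that list was not called (0.0906).

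Interferon-stimulated genes fell at day 56 (camera adjusted p = 3.49e-05; adjusted p = 0.625 with an estimated correlation), with 8 of 50 lower and 1 higher over all genes and 14 lower and 1 higher adjusted over the list alone. Ifi27 fell from 110 ± 46.4 to 8.50 ± 2.71 CPM (SD, n = 3), by 3.70 on the log2 scale (SE 0.43, adjusted p = 0.00404), and the GTPase gene Ifi47 by 1.71 (SE 0.25, adjusted p = 0.00985). Ifit1, on the same list, rose by 7.53 (SE 1.40, adjusted p = 0.0198). B cell markers fell (adjusted p = 0.000547; 0.716 with an estimated correlation), with 2 of 22 lower over all genes and 4 adjusted over the list alone. Those over all genes were Tnfrsf13c, the receptor for the survival factor BAFF (-1.77, SE 0.23, adjusted p = 0.00601), and Cd79b of the B cell receptor (-1.60, SE 0.33, adjusted p = 0.0257). NK and cytotoxic markers rose (adjusted p = 0.00892; 0.740 with an estimated correlation), with 2 of 26 past the threshold and 3 adjusted over the list alone. Those over all genes were Tbx21 (1.31, SE 0.31, adjusted p = 0.0407) and Il2rb (1.17, SE 0.29, adjusted p = 0.0424). The list was not called without normoxia replicate 1 (0.447) or day 56 replicate 3 (0.0763). The chemokine receptors Ccr8 (2.79, SE 0.48, adjusted p = 0.0148) and Ccr4 (1.66, SE 0.32, adjusted p = 0.0219) rose, while Ccr3 (-1.86, SE 0.48, adjusted p = 0.0471) and Ccr6 (-1.64, SE 0.40, adjusted p = 0.0411), outside the naming rule and named after their values were seen, fell. The list of chemokine receptors was not called (adjusted p = 0.838; of 16 tested, 2 higher and 2 lower over all genes). Mmp9 (2.18, SE 0.36, adjusted p = 0.0138) and the decoy receptor Il1r2 (3.71, SE 0.68, adjusted p = 0.0193) rose. The latter pair are on the neutrophil list, which was not called at day 56 (adjusted p = 0.152; 13 of 22 fold changes above 0 and 9 below). Over all genes 2 of its members passed as higher and 1 as lower.

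Mitochondrially encoded genes fell at day 56 (camera adjusted p = 0.000357; 0.651 with an estimated correlation), with 0 of 13 past either threshold and all 13 lower. Their mean log2 CPM was 10.17 in day 56 replicate 1, within the normoxia range of 10.11 to 10.43, and 9.06 and 8.96 in day 56 replicates 2 and 3. Nuclear oxidative phosphorylation genes (adjusted p = 0.000213; 0.740 with an estimated correlation; 1 of 35 lower over all genes, 0 adjusted over the list alone) and ribosomal protein genes (adjusted p = 0.00106; 0.874 with an estimated correlation; 1 of 79 higher over all genes, 0 adjusted over the list alone) fell as lists. For the latter pair the level of normoxia replicate 1 given above lay below all 6 Sugen-hypoxia libraries, and the ribosomal list was not called without normoxia replicate 2 (0.128) or 3 (0.118), nor with the intron share as a covariate (0.984). Erythroid markers were not called at day 56 (adjusted p = 0.613), nor were platelet (0.945) or monocyte markers (0.769).

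Other named rises at day 56 were Fam111a (4.97, SE 0.51, adjusted p = 0.00181), the phosphatase Ptpn5 (6.24, SE 1.18, adjusted p = 0.0198), Lrrc32 (2.29, SE 0.37, adjusted p = 0.0125), Bag3 (1.77, SE 0.32, adjusted p = 0.0176) and Dnajb4 (1.13, SE 0.20, adjusted p = 0.0164). Named falls were Bbs10 (-2.73, SE 0.25, adjusted p = 0.00109), B3gnt5 (-2.22, SE 0.32, adjusted p = 0.00832), Atp6v1g3 (-2.30, SE 0.45, adjusted p = 0.0229), Zfp54 (-2.10, SE 0.34, adjusted p = 0.0125), Il2ra (-0.60, SE 0.15, adjusted p = 0.0422) and Calhm5 (-2.03, SE 0.40, adjusted p = 0.0228), of whose exon reads 8.30% were uniquely mapped. Serpinb11 had 0 reads in the 3 day 56 libraries and was at least 907-fold lower than the normoxia mean (adjusted p = 0.0411), but it also had 0 reads in day 28 replicate 2 and varied within normoxia from 8.16 to 53.1 CPM.

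In all, 886 of 12447 genes passed at day 56, 3846 had an unadjusted p under 0.05, and the groups did not overlap in 30.4% of genes, where chance gives 10% on average (spread not computed). The count was 5453 without normoxia replicate 1, 93 and 119 without normoxia replicates 2 and 3, 404 and 567 without day 28 replicates 1 and 2, and 304, 85 and 109 without day 56 replicates 1, 2 and 3. DESeq2 called 2441, and 136 passed with the intron share as a covariate, which ended 25 of the 43 named calls. With it all 886 genes kept their sign, at a median of 0.876 times the log2 fold change and 1.11 times the SE. With the series of column codes as a block 791 genes passed, and within the 4 libraries of the second series, which leaves out normoxia replicate 1, 5912 did. Of the 43 named genes called, 14 passed without each library in turn: Ahrr, Fam111a, Fosb, Klf6, Klf9, Per1, Rel, Rhob, Tnfaip3, Tnfrsf13c, Ifi27, Ifi47, Bbs10 and B3gnt5. The other 29 lost their call without 1 library or more, with adjusted p up to 0.165. Calls lost numbered 29 and 23 without normoxia replicates 2 and 3, 3, 1 and 3 without day 28 replicates 1, 2 and 3, and 16, 24 and 26 without day 56 replicates 1, 2 and 3.

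**Figure D3:**
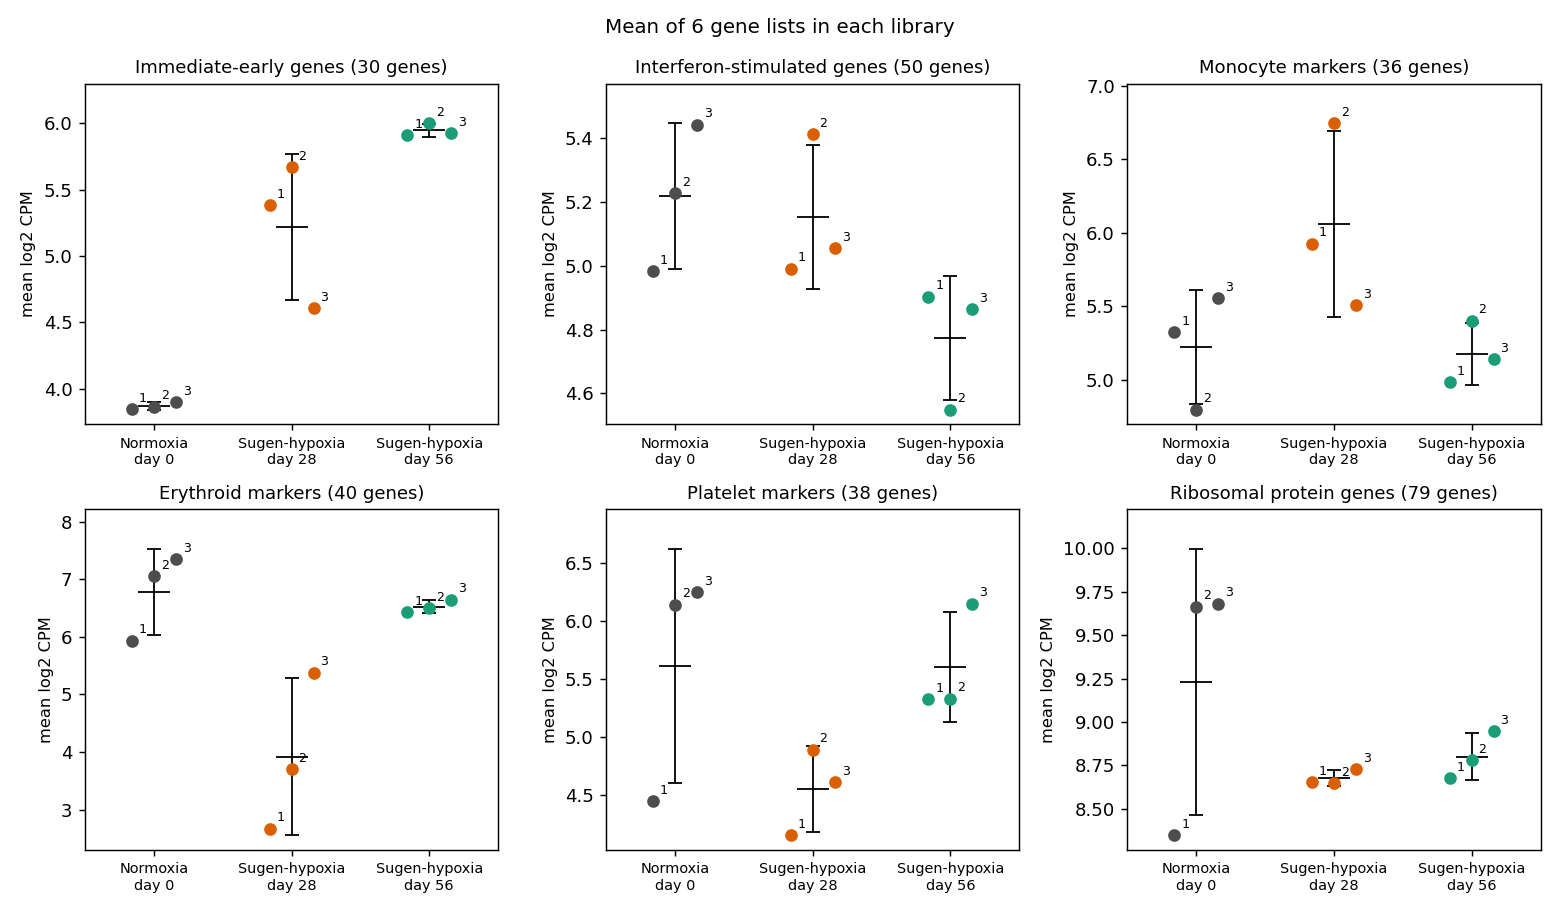
Mean log2 CPM of the tested members of 6 gene lists in each library, by group; the vertical axes do not start at 0. Points are libraries with their replicate numbers, and bars are mean ± SD of 3 libraries. The immediate-early mean is 3.84 to 3.90 in normoxia and 4.61 to 6.0 in the 6 Sugen-hypoxia libraries, while the ribosomal mean of normoxia replicate 1 (8.35) lies below all others.

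The direct comparison of the days asks which transcripts differed between day 28 and day 56 of the model. Erythroid markers were higher at day 56 (camera adjusted p = 2.90e-20; adjusted p = 0.625 with an estimated correlation), with a median log2 difference of 2.17, 4 of 40 past the threshold over all genes and 24 adjusted over the list alone. Tspo2 differed by 5.34 (SE 0.79, adjusted p = 0.0291) and the survival gene Bcl2l1 by 2.26 (SE 0.32, adjusted p = 0.0291); the globin share of the libraries is given above. Platelet markers were higher (adjusted p = 6.85e-08; 0.713 with an estimated correlation), with 0 of 38 past the threshold over all genes and 14 higher and 1 lower adjusted over the list alone. Monocyte markers were lower (adjusted p = 5.06e-08; 0.625 with an estimated correlation; median -1.21), with 0 of 36 past the threshold over all genes and 22 lower and 1 higher adjusted over the list alone. Interferon-stimulated genes were lower (adjusted p = 3.74e-06; 0.625 with an estimated correlation), with 2 of 50 lower over all genes and 9 lower and 1 higher adjusted over the list alone. Ifi27 differed by -3.72 (SE 0.43, adjusted p = 0.0147) and Ifi47 by -1.49 (SE 0.25, adjusted p = 0.0413). Tlr7, a sensor of viral RNA, was lower by -1.93 (SE 0.26, adjusted p = 0.0285), Naip2 by -2.12 (SE 0.29, adjusted p = 0.0285) and Dusp6 by -1.25 (SE 0.19, adjusted p = 0.0291).

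Immediate-early genes were higher at day 56 than at day 28 (camera adjusted p = 1.20e-06; adjusted p = 0.625 with an estimated correlation), with 1 of 30 past the threshold over all genes and 11 adjusted over the list alone. NK and cytotoxic markers were higher (adjusted p = 4.15e-06; 0.625 with an estimated correlation), with 0 of 26 past the threshold over all genes and 9 adjusted over the list alone. The chemokine receptors Ccr4 (2.19, SE 0.32, adjusted p = 0.0291) and Ccr8 (2.94, SE 0.46, adjusted p = 0.0325) were higher, as were Rasgef1b (2.75, SE 0.19, adjusted p = 0.000761), Tmcc2 (4.57, SE 0.56, adjusted p = 0.0195), Abca4 (3.35, SE 0.58, adjusted p = 0.0424), Dnah2 (3.07, SE 0.46, adjusted p = 0.0291), Slit1 (2.51, SE 0.43, adjusted p = 0.0413) and Cenpw (2.54, SE 0.44, adjusted p = 0.0448). T cell markers (adjusted p = 0.00729; 0.740 with an estimated correlation; 0 of 26 past either threshold), cell cycle genes (0.00546; 0.713 with an estimated correlation; 0 of 42 over all genes, 2 adjusted over the list alone) and glucocorticoid response genes (0.0360; 0.567 with an estimated correlation; 0 of 12 over all genes, 1 adjusted over the list alone) were higher as lists. Mitochondrially encoded genes were lower (0.00444; 0.713 with an estimated correlation; 0 of 13 past either threshold), but not called without day 28 replicate 3 (0.112). Day 56 replicate 1 (10.17) lay within the day 28 range of 9.69 to 10.49 in their mean. T cell markers were not called without day 28 replicate 2 (0.490) or day 56 replicate 3 (0.0535), nor with the intron share as a covariate (0.406). The T cell list turned downwards with the globin share as a covariate (0.773) and with day 28 replicates 1 and 2 left out together (0.172). Cell cycle genes were not called without day 28 replicate 1 (0.0549) or 3 (0.0625), nor with the intron share (0.189). Glucocorticoid response genes were not called without normoxia replicate 1 (0.0551), day 28 replicate 2 (0.0976) or day 56 replicates 2 (0.0555) or 3 (0.0760). They were also lost with uniquely mapped reads (0.0783), with the intron share (0.0906) and without day 28 replicates 1 and 2 (0.0864).

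Lower at day 56 than at day 28 were also Dync2h1 (-1.45, SE 0.21, adjusted p = 0.0291), Zscan12 (-1.26, SE 0.22, adjusted p = 0.0421) and Lpar6 (-1.32, SE 0.21, adjusted p = 0.0330). Npy was higher (3.38, SE 0.56, adjusted p = 0.0364). Lpar6 and Npy are uncertain because 0.0728% and 5.07% of their exon reads were uniquely mapped. In all, 68 of 12447 genes passed, 53 higher and 15 lower at day 56. An unadjusted p under 0.05 was found for 2302 genes, and the groups did not overlap in 35.2% of genes, where chance gives 10% on average (spread not computed). The count was 1002 without normoxia replicate 1, 39 and 40 without normoxia replicates 2 and 3, 14, 10 and 263 without day 28 replicates 1, 2 and 3, and 11, 3 and 4 without day 56 replicates 1, 2 and 3. DESeq2 called 1084. With the log2 share of the 5 globin-locus genes as a covariate edgeR called 0 genes and 975 had an unadjusted p under 0.05. On that scale day 28 replicates 1 and 2 (1.42% and 4.83%) lie far from the other libraries (29.0% to 56.3%). The covariate is therefore poorly separated from the day 28 group. With that covariate all 68 genes kept their sign, at 0.596 to 1.44 times the log2 fold change (median 1.03), and their SE was a median 1.60 times as large. Rasgef1b was 2.55 (SE 0.31, adjusted p = 0.0591), against 2.75 (SE 0.19) without it, and Tspo2 3.97 (SE 1.35, adjusted p = 0.583), against 5.34 (SE 0.79). Of the 19 named genes called, Rasgef1b alone passed without each library in turn. The other 18 lost their call without any 1 of the day 56 libraries, 14, 15 and 1 without day 28 replicates 1, 2 and 3, and 7 without normoxia replicate 2 or 3, with adjusted p up to 0.173.

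The joint test of both days against normoxia called 617 genes, and 4210 had an unadjusted p under 0.05. It called 6561 without normoxia replicate 1, 68 and 92 without normoxia replicates 2 and 3, 122 and 191 without day 28 replicates 1 and 2, and 68, 29 and 30 without day 56 replicates 1, 2 and 3. The day 28 and day 56 fold changes correlated over genes with r = 0.623. In 20 simulations of unchanged groups, with the controls also drawn from the normoxia means, r was 0.508 (SD 0.0116). Genes were drawn independently there, without the deviation of normoxia replicate 1, so this SD covers neither. The observed correlation is across genes, which are not independent replicates. The covariance was 0.382 against 0.0757 in the simulations, and the spread of the controls alone accounts for 0.118. The simulated value lay below the latter, so the excess over the simulations may overstate what the days share. Signs were the same in 78.3% of genes, against 67.1% in the simulations. The 11 genes called at both days were all higher, where independent lists would share 0.376 higher and 0.185 lower. They were Ahrr, Dpysl5, Erp27, Fam111a, Gpr15, Jun, Klf6, Rhob, Tnfaip3 and, outside the naming rule and named after their values were seen, Phlda1 and Tob1. The 3 controls were not split between the days, so part of the excess may come from the shared controls. The correlation was 0.765 without normoxia replicate 1, 0.504 with the intron share and 0.419 with the globin share as a covariate, and 0.443 without day 28 replicates 1 and 2. Unchanged groups were not simulated under these settings, and the last 3 values lie below the simulated 0.508 of the full set.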

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

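Chosen only after the results were seen were the tests of carried-over red cells, of the share of the 5 top genes, of Sugen-hypoxia at day 28 on the erythroid list, of a wrong label, of the column codes, of monocytes and of blood handling, and the settings with the 5 top genes out of library sizes, with the intron or globin share as a covariate and without day 28 replicates 1 and 2.

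Day 56 and day 28 differed in 68 genes, by the direct test of the Sugen-hypoxia groups. No controls of those days were measured, so an effect of age or of the day 28 code series is not separated from the model. With the log2 globin share as a covariate, which is poorly separated from the day 28 group, edgeR called 0 genes and 975 had an unadjusted p under 0.05. Without it DESeq2 called 1084 and limma-voom 84. All 68 genes kept their sign with that covariate, at 0.596 to 1.44 times the log2 fold change (median 1.03), and their SE was larger (median 1.60 times). Higher at day 56, on the log2 scale, were Tspo2 (5.34), Tmcc2 (4.57), Npy (3.38), Abca4 (3.35), Dnah2 (3.07), Ccr8 (2.94), Rasgef1b (2.75), Cenpw (2.54), Slit1 (2.51), Bcl2l1 (2.26) and Ccr4 (2.19). Lower were Ifi27 (-3.72), Naip2 (-2.12), Tlr7 (-1.93), Ifi47 (-1.49), Dync2h1 (-1.45), Lpar6 (-1.32), Zscan12 (-1.26) and Dusp6 (-1.25). By the preset-correlation list test, the days differed with median log2 differences of 2.17 in erythroid, 1.25 in platelet, 0.78 in NK and cytotoxic, 0.27 in T cell and -1.21 in monocyte markers. The medians were 0.68 in immediate-early, 0.46 in glucocorticoid response, 0.14 in cell cycle, -0.42 in interferon-stimulated and -0.48 in mitochondrially encoded genes. None of these 10 list calls held with an estimated correlation (adjusted p = 0.567 to 0.740), and the T cell list turned downwards with the globin share (adjusted p = 0.773) and without day 28 replicates 1 and 2 (0.172).

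Outside the tested counts, some read sums over 3 libraries lay above those of normoxia; these differences were not tested. Ahrr had 302 intron reads at day 28 and 127 at day 56, against 3 in normoxia. Cyp1a1, below the count filter, had 20 and 10 exon reads against 2, which is 0.176 ± 0.144 and 0.121 ± 0.0425 against 0.0278 ± 0.0481 CPM (SD, n = 3). Cyp1b1 had 8 and 9 against 1, which is 0.0733 ± 0.00829 and 0.109 ± 0.136 against 0.0123 ± 0.0212 CPM (SD, n = 3).

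Erythroid RNA was low at day 28. Counts taken by the 5 top genes would lower other genes where that share is high, but the highest day 28 library lay 14.0 percentage points below the lowest normoxia library. Leaving these and the mitochondrial genes out of library sizes moved the median of the other erythroid genes only from -2.56 to -2.53 and so tested little. Fewer red cells carried over would lower all erythroid transcripts alike: the globin-locus genes fell by 2.93, which differs from that median by -0.37 with an SD over members of 1.18, but the gap was -1.67, -0.96 and 0.05 in day 28 replicates 1, 2 and 3. Carry-over thus stays open and cannot be told apart from an effect of Sugen-hypoxia at day 28, which would lower the same list; the exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, bears on neither.

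Normoxia replicate 1 lay with the Sugen-hypoxia libraries on the first component. Its highest correlation over genes was with day 28 replicate 3 (r = 0.972). It was 0.946 to 0.958 with the other Sugen-hypoxia libraries, and 0.934 and 0.932 with normoxia replicates 2 and 3. In 83.5% of the 7057 genes called without normoxia replicate 1, this library lay nearer to the Sugen-hypoxia mean than to normoxia replicates 2 and 3. This was the outcome set afterwards for a wrong label. Any other cause of its position on the first component would give the same outcome, so it does not decide between them. Against its being a Sugen-hypoxia sample, in a test and a bound set afterwards, its immediate-early mean (3.84) lay 0.76 below the lowest Sugen-hypoxia library. The 3 normoxia libraries span 0.0557, but the day 28 libraries run from 4.61 to 5.67, a range wider than that gap. The immediate-early mean therefore weighs little by itself. Normoxia replicate 1 also had 0 Ahrr exon reads, where the lowest Sugen-hypoxia library had 86. A wrong label is not settled, and a sample from outside these groups stays open. The library of the same code series, day 56 replicate 1, shared little of its deviation over genes (r = 0.0653), which argues against a batch in the column codes. The intron share cannot be told apart from other differences between libraries: within the Sugen-hypoxia groups it went with the position on that axis with r = 0.455 (exact one-sided permutation p = 0.278, 6 libraries).

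Immediate-early genes were higher in all 6 Sugen-hypoxia libraries. More monocytes as the only source would need the list to fall with the monocyte markers from day 28 to day 56 (median -1.21). Its median instead rose by 0.68. The SE of the list mean (0.13) takes the genes as independent and does not measure the spread between samples. The list mean was 4.61 to 5.67 in the day 28 libraries and at least 5.91 at day 56. Camera with an estimated correlation did not call this difference (adjusted p = 0.625). Monocyte markers lay above the normoxia range in day 28 replicates 1 and 2 but not in replicate 3. A monocyte share in the day 28 rise stays open. The intron share as a covariate left a median of 1.60 at day 56 (1.87 without it), with 10 members still called. Handling of the blood before lysis could induce these genes and cannot be told apart from the groups, since no label gives handling times: the lowest Sugen-hypoxia library lay 0.71 above the highest normoxia library. An effect of the model itself, of age or of the hour of sampling stays open and untested.

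For each pair of groups there are only 10 splits of the libraries, too few for a share under 0.05: the real split gave 16, 886 and 68 genes (1 of 10 each), and the highest other split 1, 0 and 1. Of 100 splits into 3 groups of 3, drawn from 280, 1 gave as many genes in the joint test as the real 617, the real split itself. The highest other gave 108. That argues against a random grouping of these libraries as the source of that count. The joint test responds to any difference between the 3 groups, so it cannot part the model from the day 28 code series or from technical replicates. For the gene lists a random grouping stays open: 17 of 100 splits gave at least the real 38 calls among the 93 tests of a list in a comparison. The highest other gave 47 and the median split 31.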

How the results depend on the processing

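Chosen after seeing the data were the uniquely mapped reads, both covariates, the 5 top genes out of library sizes, day 28 replicates 1 and 2 left out together, and both settings of the column codes. Except where the construction shows it (fewer libraries, a stricter threshold, another number of genes), the cause was not tested.

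The day 28 count of 16 was 8 with RLE factors, 79 with upper-quartile factors, 1762 with DESeq2, 8 with limma-voom, 151 without a filter, 8 with a stricter filter, 72 with uniquely mapped reads, 1 with the intron share and 1 with the globin share as a covariate, 5 without day 28 replicates 1 and 2, 2 with only the groups compared, 5 at an adjusted p of 0.01, and 2 to 5732 leaving out 1 library. The day 56 count of 886 was 2441 with DESeq2, 136 with the intron share, 491 with the globin share, 330 without day 28 replicates 1 and 2, 348 with only the groups compared, 5912 in the 4 libraries of the second code series, 79 at 0.01, and 85 to 5453 leaving out 1 library. The count of 68 between the days was 1084 with DESeq2, 0 with the globin share, 14 without day 28 replicates 1 and 2, 590 with only the groups compared, 4 at 0.01, and 3 to 1002 leaving out 1 library. The joint count of 617 was 3320 with DESeq2, 241 with the intron share, 140 with the globin share, 132 without day 28 replicates 1 and 2, and 29 to 6561 leaving out 1 library. The correlation of 0.623 was 0.504 with the intron share, 0.419 with the globin share, 0.443 without day 28 replicates 1 and 2, and 0.558 to 0.765 leaving out 1 library. At day 28 all 16 genes kept their sign with the intron and the globin share, at a median of 0.768 and 0.870 times the log2 fold change and 1.45 and 1.38 times the SE. Apart from the replicate block, given next, the other settings run left the counts within 1.5 times and the correlation within 0.1.

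The replicate numbers did not pair the samples: same-number correlations of deviations ran from -0.146 to 0.167, and 4 of 9 libraries correlated best with their own number. As a block they gave 225 genes at day 28, 537 at day 56 and 184 between the days, and ended the list calls of AHR targets at day 28 (adjusted p = 0.0719) and hypoxia targets at day 56 (0.0554).

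Of the 38 list calls (24 up and 14 down), 0 held with an estimated correlation; fry made 7 calls. Over 684 values, 573 kept the call and direction, 106 lost the call and 5 turned: with the intron share, at day 28, oxidative phosphorylation (adjusted p = 0.584), platelet (0.0850) and ribosomal genes (9.91e-05); between the days T cell markers with the globin share (0.773) and without day 28 replicates 1 and 2 (0.172). Over 2047 values of 86 named-gene results, 1587 kept their side and direction, 425 lost the call, 16 gained it and 19 changed sign, all of results that were not called. These were Tiparp at day 56 in the 4 libraries of the second code series (-0.059), Nqo1 between the days without day 28 replicates 1 and 2 (0.13), and Ahrr and Ahr between the days. Ahrr (-0.20) was 0.18 with the intron share, 0.42 with the globin share, 0.26 without day 28 replicates 1 and 2, and -0.44 to 0.054 leaving out 1 library. Ahr (0.00024) was -0.0033 with RLE factors, -0.00042 with DESeq2, -0.015 with limma-voom, -0.014 without a filter, -0.011 with globin and mitochondrial genes out of library sizes, -0.0057 with the replicate block, -0.044 with the globin share, -0.0013 without day 28 replicates 1 and 2, and -0.13 to 0.12 leaving out 1 library. In the simulations, drawn with the dispersions of the main fit that includes normoxia replicate 1, 2-fold changes were mostly missed. They do not show what 3 libraries a group would miss without that library's deviation.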

Other observations

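The counts of genes that switch within a group were chosen after the data were seen; the list tests were planned.

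Of the 31 lists, 11 were called in no comparison; their smallest adjusted p by camera over the 3 comparisons is given. Genes of inherited pulmonary hypertension reached 0.102, dendritic cell markers 0.134 and AHR pathway components 0.260, each at day 28. T helper 17 genes reached 0.270, plasma cell markers 0.208, regulatory T genes 0.455, heat shock genes 0.712 and basophil, eosinophil and mast cell markers 0.576, each between the days. Endothelial and stromal markers reached 0.437 and MHC class II genes 0.482 at day 28. Chemokine receptors reached 0.838 at day 56, where the test pointed up and the median was -0.01; the members that passed are given above.

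The median, the mean and the test of a list had 1 sign in each of the 38 calls. They differed in sign in lists that were not called: at day 28 in basophil, eosinophil and mast cell markers, chemokine receptors, regulatory T genes and interferon-stimulated genes (median 0.01, mean -0.04, adjusted p = 0.794). At day 56 they differed in genes of inherited pulmonary hypertension, chemokine receptors, dendritic, plasma and regulatory T cell genes and heat shock genes. Between the days they differed in NF-kB inflammatory genes, chemokine receptors, myeloid suppressor genes and nuclear oxidative phosphorylation genes.

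Within groups of replicates, 22 genes had 0 or 1 read in 1 library and 5 CPM or more in another. Of these, 13 had under 1% uniquely mapped exon reads, against 2.60% of all tested genes, and 3 had over 90%: AABR07001902.1, Adamts13 and Serpinb11. Adamts13, the protease that cleaves von Willebrand factor (chromosome 3, 5519989 to 5558166, rn6), was at 0 CPM in normoxia replicate 1 and day 28 replicate 3 and between 12.6 and 41.6 CPM in the other libraries. Serpinb11 was at 0 CPM in day 28 replicate 2 and all day 56 libraries, and at 4.39 and 13.9 CPM in the other day 28 libraries.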
